A study of Homo sapiens with 6 samples.

How the data were processed

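Bulk RNA sequencing was done on A549 cells, an established human non-small cell lung cancer line, in 6 libraries. Per the labels, 3 libraries came from cells transfected with a control siRNA (si-NC) and 3 from cells transfected with an siRNA against AUH (si-AUH). RNA was taken 48 hours after transfection, with Trizol, and libraries were made from total RNA with a strand-marking NEBNext kit, per the labels' protocols. The labels call the 3 samples of each group biological replicates.

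The authors deposited 1 table of FPKM values (fragments per kilobase of gene with library size divided out) for 62191 genes, with gene symbols, positions, lengths and biotypes. The genome build was GRCh38 (hg38), per the submitters' processing notes. The aligner, the counting tool, the annotation release and whether the counting used strand are not given in the sources used here. Reads of overlapping, antisense or near-identical genes may therefore be shared. Reported genes that overlap another gene with a mean of at least 1 FPKM are named as uncertain. Multiplying each FPKM value by its gene's length gave whole multiples of 1 step per library for 100% of positive values, within a tolerance of 0.1 of a read. These recovered reads summed to between 13838375 and 14843429 per library. They served to give depth and as an alternative test, not as the main test.

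Values were analysed as log2(FPKM + 0.5) for the 11855 genes with a mean of at least 1 FPKM over the 6 libraries, of which 9950 are protein coding. Groups were compared with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, two-sided, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes from this model are on the log2(FPKM + 0.5) scale, which understates the change of low genes. Folds given beside group means are ratios of mean FPKM. With 3 libraries against 3, an exact two-sided permutation test of a single value cannot go below p = 0.1.

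The design, the alternatives, 37 gene lists (1086 symbols) and the rule for named genes were fixed before the data were examined. AUH itself was left out of the lists. The 32 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists. camera with an estimated correlation and fry were alternatives. The rule named AUH; the 8 largest rises and 8 largest falls past the threshold with no overlap between groups and a gene symbol; HMGCS1, SQLE, SREBF2, BCAT1, BCKDHA, MCCC1 and others; and up to 4 changed members of each list, or up to 2 with the smallest p where none passed. Where 5 or fewer members of a list went one way, those outside the rule are named too, and these were chosen after their values were seen. Some genes that these rules take are not reported here.

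The alternatives chosen beforehand were pseudocounts of 0.1 and 1, no filter on low values, a mean of at least 5 FPKM, median-of-ratios and quantile scaling, no trend, the replicate number as a block, each library left out in turn, and an absolute log2 fold change of at least 1. Count-based tests meant for a table of raw counts were not run, because the table holds FPKM. Added after seeing the data were voom on the recovered reads, 2 libraries left out, the mitochondrial share as a covariate, removal of each library's trend on GC content and length (transcript length, and deposited gene length, which was taken up later because it followed the deviation of 2 outlying libraries more closely), and a fit on genes without 2 particular 3' UTR words.

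GENCODE release 29 supplied transcript sequences. Its gene IDs matched 93.8% of the table's genes, and 99.9% of those overlapped on the same chromosome, although 72.5% had the same start and end, so printed gene positions are those of the deposited table. The longest 3' UTR of each of 9868 tested coding genes was searched for 7-base words. Each word's z, a standardized difference in mean fold change, was taken after a fit on UTR length and GC content. It was set against 100 shuffled runs (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). Median shifts of words and their bootstrap intervals are from fold changes without that fit, resampling genes with the libraries held fixed.

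The gene test was tested on simulated counts drawn for the 11855 genes of this comparison, turned into FPKM, with 200 genes changed. It recovered 50.9% of genes changed 1.5-fold, 90.8% of those changed 2-fold and 98.6% of those changed 4-fold, and 6.12% of its calls were false. All genes were drawn with 1 dispersion (0.00728) and without libraries that stand apart, so these rates may not hold for the real libraries. A planted list changed 1.4-fold was called in 10 of 10 simulations and 0 of 310 unchanged lists was called, with genes simulated as independent. In 10 simulations on 9868 genes, a word given a fall of 0.1 on the log2 scale was the lowest word in 10.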

Results

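The transcriptomes of A549 cells treated with control siRNA (si-NC, 3 libraries) or AUH siRNA (si-AUH, 3 libraries) were compared 48 hours after transfection. Depth was similar in all libraries, from 13838375 recovered reads in si-NC replicate 3 to 14843429 in si-AUH replicate 1. Pearson correlations of log2 values were 0.964 to 0.983 within groups and 0.947 to 0.963 between groups. Transcripts of the mitochondrial genome took 12.1% of reads in si-NC replicate 1 and 11.4% in si-AUH replicate 2, against 7.75% to 8.11% in the other 4 libraries.

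The first question was whether AUH mRNA fell in the knockdown libraries. AUH encodes a mitochondrial enzyme of leucine breakdown that also binds AU-rich RNA (ENSG00000148090, chromosome 9, 91213815 to 91361918, minus strand, GRCh38). Its level was 4.46 ± 0.572 FPKM (SD, n = 3) in si-NC and 0.967 ± 0.304 FPKM (SD, n = 3) in si-AUH, or 21.7% of the control mean. Single libraries held 3.83, 4.94 and 4.61 FPKM in si-NC and 1.17, 1.11 and 0.618 FPKM in si-AUH, from 119 to 166 and from 21 to 41 recovered reads. The log2 fold change was -1.77 (SE 0.186, limma adjusted p = 0.00211). The exact permutation p was 0.1, the smallest that 3 against 3 allows.

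The second question was which other transcripts changed. INSIG1, which retains the sterol sensor SCAP in the endoplasmic reticulum, rose 5.32-fold, from 3.96 ± 0.198 to 21.1 ± 0.354 FPKM (SD, n = 3 each; limma adjusted p = 0.00013). EGR1, an immediate-early transcription factor, rose from 1.27 ± 0.353 to 5.29 ± 0.404 FPKM (SD, n = 3 each; limma adjusted p = 0.00162). Among the falls, CA12, a membrane carbonic anhydrase, went from 229 ± 11.9 to 54.8 ± 2.58 FPKM (SD, n = 3 each; limma adjusted p = 0.000186). The keratin gene KRT80 fell 4.26-fold, POFUT1, which adds fucose to Notch receptors, 3.96-fold, and STARD7, a phosphatidylcholine transfer protein, 3.75-fold. VPS25, a subunit of the ESCRT-II complex, fell 3.96-fold, HR, a transcriptional corepressor, 3.99-fold, and the cytokine gene IL11 4.24-fold. All 7 of these falls other than AUH carried CAGGGAC or AGGGACA in the 3' UTR, as did 37.5% of coding genes that fell, 14.4% of those that rose and 19.8% of those not past the threshold.

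In all, 819 genes were higher and 1189 lower in si-AUH among 11855 tested (limma, adjusted p under 0.05). Of these, 69 rose and 135 fell by at least 1 on the log2 scale. The groups did not overlap at 37.9% of tested genes, where chance alone gives 10%. The remaining 6 of the 8 largest rises were small or antisense transcripts with few reads. SNORD73B, RNU6-190P, MIR1285-1, MIR324 and RNU6-20P had at most 7 recovered reads in any library, and each overlaps another gene of the table. MIR1285-1, MIR324 and RNU6-20P lost their calls in 4, 5 and 4 of the 6 leave-one-out fits. SERTAD3-AS1 had at most 21 reads and overlaps SERTAD3, so these 6 levels are uncertain. The counts were 371 higher and 628 lower without si-NC replicate 2, 431 and 650 without si-NC replicate 3, 394 and 677 without si-AUH replicate 1, and 327 and 564 without si-AUH replicate 3. Without si-NC replicate 1 and si-AUH replicate 2, the libraries with more mitochondrial RNA, 1228 genes were higher and 1682 lower.

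The series title names cholesterol biosynthesis, and most of its enzymes rose. Of 21 tested genes of the pathway, 15 were higher, 1 was lower and 5 did not pass the threshold; adjusted over the list alone, 18 were higher and 1 lower. MSMO1, a sterol C4-demethylation enzyme, rose 3.32-fold, from 9.33 ± 0.261 to 31.0 ± 1.89 FPKM (SD, n = 3 each). HMGCS1, which makes HMG-CoA, rose 2.75-fold, from 15.3 ± 0.593 to 42.0 ± 3.84 FPKM (SD, n = 3 each). SQLE, the squalene epoxidase, rose 2.02-fold, from 21.4 ± 1.01 to 43.3 ± 3.14 FPKM (SD, n = 3 each). EBP, the sterol isomerase, named after its values were seen, was the 1 member that fell, from 12.4 ± 2.49 to 6.54 ± 0.727 FPKM (SD, n = 3 each). Its call was lost without si-NC replicate 2 or without si-NC replicate 3, with log2 fold changes of -1.03 to -0.76 over the leave-one-out fits. The median log2 fold change of the list was 0.62 (limma camera, adjusted p = 2.58e-10). The list missed the threshold with an estimated correlation (limma camera, adjusted p = 0.0685). Without the 2 libraries with more mitochondrial RNA, 13 of its genes were higher and the median was 0.54.

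**Figure D1:**
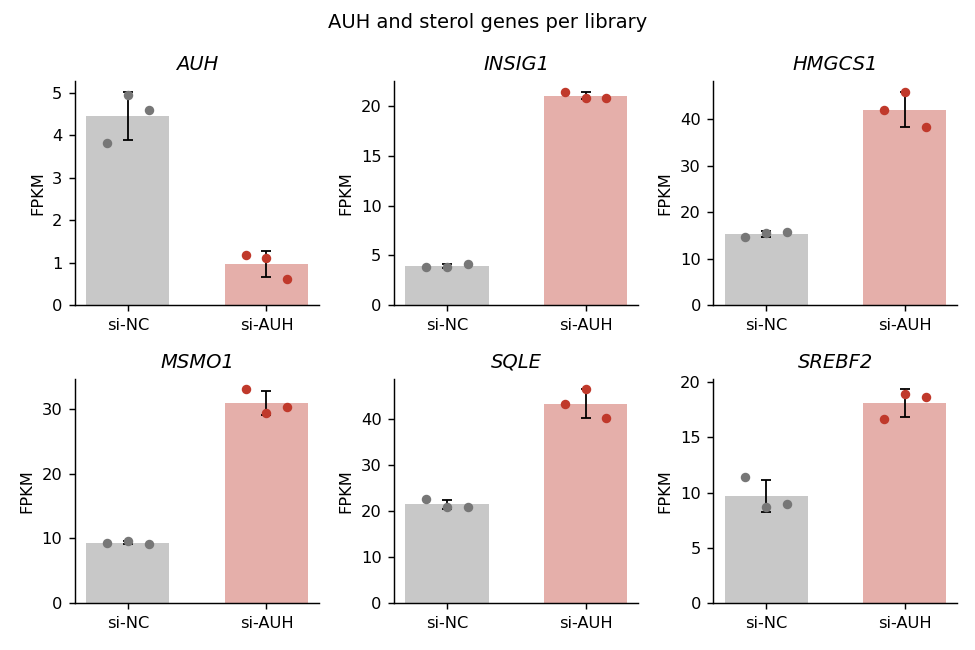
FPKM of AUH and 5 sterol genes in each library (points) with group means (bars) and SDs (error bars, n = 3), each panel on its own linear axis from 0. AUH is lower in every si-AUH library, and the 5 sterol genes are higher in every si-AUH library than in any si-NC library, SREBF2 by the smallest ratio of means (1.87-fold) and INSIG1 by the largest (5.32-fold).

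Genes that regulate sterols moved in both directions. Of 19 tested genes of sterol regulation and uptake, 2 rose, INSIG1 and SREBF2, and SREBF1 fell. SREBF2, the transcription factor that drives the pathway above, went from 9.69 ± 1.49 to 18.1 ± 1.25 FPKM (SD, n = 3 each; limma adjusted p = 0.00496). SREBF1 went from 24.2 ± 1.28 to 18.3 ± 0.956 FPKM (SD, n = 3 each; limma adjusted p = 0.0163). It lost its call in 4 of 6 leave-one-out fits, without si-NC replicate 2 or 3 or si-AUH replicate 1 or 3, where its highest limma adjusted p was 0.0713. The list was not past the threshold in camera (limma, adjusted p = 0.138) and passed in fry (limma, adjusted p = 0.00247). Of 9 genes of sterol efflux and esterification, CH25H, which makes 25-hydroxycholesterol, rose 2.65-fold, while LPCAT3, a lysophospholipid acyltransferase, fell 2.91-fold and OSBP, an oxysterol binding protein, 1.69-fold. NCEH1, a cholesteryl ester hydrolase, also passed the threshold (log2 fold change 0.54), although it lost its call in 5 of 6 leave-one-out fits. Among 20 genes of fatty acid synthesis, 4 rose and 2 fell, with a list median of -0.00096 and a mean of 0.08 (limma camera, adjusted p = 0.249). The desaturase gene SCD rose 1.61-fold and the lipin gene LPIN1 1.67-fold, while the acyl-CoA synthetase gene ACSL4 fell 2.03-fold and the desaturase gene FADS1 1.53-fold. ELOVL7 and ELOVL6 also rose, and were named after their values were seen. SCD lost its call without si-NC replicate 2 or 3, ACSL4 without si-AUH replicate 1 or 3, and ELOVL7 and ELOVL6 in 3 and 5 leave-one-out fits.

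Branched-chain amino acid breakdown, the other pathway in the title, did not move as a list. Of 23 tested genes, 1 was higher, 1 lower and 21 not past the threshold, with the same counts adjusted over the list alone. The median log2 fold change was 0.03 (limma camera, adjusted p = 0.866). SLC25A44, the mitochondrial carrier of these amino acids, fell from 6.41 ± 0.503 to 3.40 ± 0.0469 FPKM (SD, n = 3 each; limma adjusted p = 0.00189). BCAT2, the mitochondrial aminotransferase, went from 19.4 ± 1.25 to 24.8 ± 1.33 FPKM (SD, n = 3 each; limma adjusted p = 0.0297). BCAT2 kept its call only without si-AUH replicate 2 among the leave-one-out fits, with log2 fold changes of 0.30 to 0.39. The cytosolic aminotransferase BCAT1 was at 3.75 ± 0.487 and 4.54 ± 0.741 FPKM (SD, n = 3 each; limma adjusted p = 0.274). MCCC1, a subunit of the carboxylase upstream of AUH in leucine breakdown, was at 2.50 ± 0.216 and 2.30 ± 0.313 FPKM (SD, n = 3 each; limma adjusted p = 0.609). BCKDHA was listed at 0, 0.0598 and 0.0317 FPKM in si-NC and at 0.0288, 0.062 and 0.237 FPKM in si-AUH, from 0 to 8 recovered reads. It was not tested, and because the authors' counting is not given, these are values as listed and no measure of absence.

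Many cell cycle genes fell in si-AUH. Of 40 genes of G2 and mitosis, 19 fell and none rose; adjusted over the list alone, 32 fell. The mitotic kinase gene AURKA fell 2.72-fold, from 58.5 ± 4.64 to 21.5 ± 0.763 FPKM (SD, n = 3 each), FOXM1, a mitotic transcription factor, 2.11-fold, and cyclin B2 (CCNB2) 1.68-fold. Of 45 genes of DNA replication, 25 fell and none rose; adjusted over the list alone, 30 fell and 2 rose. The helicase subunit MCM6 fell 2.01-fold, MCM10 1.90-fold and thymidine kinase TK1 1.71-fold. The list medians were -0.41 (limma camera, adjusted p = 1.61e-10) and -0.44 (limma camera, adjusted p = 4.27e-10). With an estimated correlation neither passed (limma camera, adjusted p = 0.123 and 0.101). AURKA, FOXM1, MCM6, MCM10 and TK1 carry CAGGGAC or AGGGACA in the 3' UTR. Among genes without either word, 19 of 36 and 23 of 41 genes of these lists fell and 1 of the latter rose, with medians of -0.41 and -0.40 (limma camera, adjusted p = 2.8e-10 and 1.46e-09). Leaving out genes with a word does not remove indirect effects of silenced mRNAs, which were not tested. Without the 2 libraries with more mitochondrial RNA, 31 genes of G2 and mitosis were lower.

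Some p53 targets, immediate-early genes and NF-kB genes rose. Of 29 p53 targets, 9 rose and 2 fell, and adjusted over the list alone 18 rose and 2 fell. BTG2, an antiproliferative gene, rose 3.33-fold, the proapoptotic gene BBC3 2.25-fold and SESN1, a stress-inducible inhibitor of mTORC1, 2.34-fold. DDB2 and FDXR, named after their values were seen, were the 2 that fell, and they lost their calls in 6 and 5 of the 6 leave-one-out fits. Of 26 immediate-early genes, 12 rose and 1 fell (14 and 1 adjusted over the list alone). Besides EGR1, the rises held ATF3, a stress-induced transcription factor, at 2.85-fold, and DUSP5 and DUSP6, phosphatases of the ERK kinases, at 2.22-fold and 2.46-fold. The nuclear receptor gene NR4A1, named after its values were seen, fell 1.90-fold. Of 22 NF-kB and inflammatory genes, 9 rose and IL11 fell (10 and 1 adjusted over the list alone). TNFAIP3, a feedback inhibitor of NF-kB, rose 2.59-fold and NFKB2 2.14-fold. The 3 lists had medians of 0.38, 0.34 and 0.45 (limma camera, adjusted p = 2.42e-07, 1.75e-05 and 5.27e-05). With an estimated correlation none passed (limma camera, adjusted p = 0.0685, 0.336 and 0.336). Without the 2 libraries with more mitochondrial RNA, 14 p53 targets were higher and 2 lower.

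Some genes of the tricarboxylic acid cycle, oxidative phosphorylation and the mitochondrial ribosome fell. Of 26 genes of the tricarboxylic acid cycle, 6 fell and 1 rose (13 and 1 adjusted over the list alone). OGDH, a subunit of the oxoglutarate dehydrogenase complex, fell 1.92-fold, and the cytosolic dehydrogenase gene IDH1 rose 1.45-fold. Of 66 nuclear genes of oxidative phosphorylation, 6 fell and 60 did not pass (4 adjusted over the list alone), and of 73 mitochondrial ribosome genes 6 fell (2 adjusted over the list alone), MRPL35 by 2.18-fold. Of all 11855 tested genes 1189 fell, so the shares of called falls in these last 2 lists were no higher than among all genes. The medians of the 3 lists were -0.26, -0.20 and -0.15 (limma camera, adjusted p = 0.00384, 0.00492 and 0.014). With an estimated correlation none passed (limma camera, adjusted p = 0.336, 0.792 and 0.78). In fry the last 2 missed the threshold (limma fry, adjusted p = 0.331 and 0.264). Oxidative phosphorylation and mitochondrial ribosome lists also lost their calls without si-AUH replicate 2, with medians of -0.025 and -0.045. They lost them without si-NC replicate 2 (medians -0.14 and -0.11) and without si-NC replicate 3 (-0.14 and -0.096). Without both libraries with more mitochondrial RNA, si-NC replicate 1 and si-AUH replicate 2, all 3 lists passed (limma camera, adjusted p = 0.00118, 0.000369 and 0.0304), with 13, 19 and 14 genes lower, 1, 0 and 1 higher, and medians of -0.26, -0.165 and -0.115. Of 13 protein-coding genes of the mitochondrial genome, 0 passed the threshold in limma, with a median of -0.08 (limma camera, adjusted p = 0.768); MT-CO2 was at 11730 ± 1347 and 9967 ± 595 FPKM (SD, n = 3 each).

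The remaining 3 called lists were autophagy, apoptosis and hypoxia. Of 25 autophagy and lysosome genes, 4 rose and 1 fell (7 and 2 adjusted over the list alone), with MAP1LC3B, an autophagosome protein, at 1.75-fold. ATP6V1H rose and ATP6V1A fell, each losing its call in 5 of 6 leave-one-out fits. Of 21 apoptosis genes, 6 rose and 2 fell (8 and 2 adjusted over the list alone); MCL1, which opposes apoptosis, rose 1.86-fold. BCL2L1 fell, and it lost its call in 3 of the 6 leave-one-out fits. Of 17 hypoxia genes, 4 rose and 2 fell (9 and 3 adjusted over the list alone). KDM3A, a histone demethylase, rose 1.59-fold and P4HA1, a collagen hydroxylase, 1.41-fold. EGLN3 and BNIP3L rose and ERO1A fell besides CA12, and these 3 lost their calls in 2, 2 and 3 of the leave-one-out fits; the last 2 were named after their values were seen. The medians were 0.26, 0.27 and 0.26 (limma camera, adjusted p = 0.00246, 0.0122 and 0.018). With an estimated correlation none passed (limma camera, adjusted p = 0.336, 0.336 and 0.344). The hypoxia list lost its call without si-NC replicate 1 (median 0.21; limma camera, adjusted p = 0.0539), in fry (limma fry, adjusted p = 0.218) and at a mean of at least 5 FPKM (limma camera, adjusted p = 0.14). Without the 2 libraries with more mitochondrial RNA, 8 autophagy, 9 apoptosis and 7 hypoxia genes were higher and 2, 2 and 3 lower.

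Other genes named above that carry CAGGGAC or AGGGACA in the 3' UTR were EBP, OSBP, FADS1, OGDH, MRPL35, ATP6V1A and FDXR, which fell, and EGR1, SREBF2, SCD, BBC3, DUSP5 and DUSP6, which rose. Some of the genes above overlap another expressed gene, and their levels are uncertain because reads of both may be shared. The use of strand in counting is not given, and strand cannot separate EGLN3, CCNB2 or MIR33B, within SREBF1, from the overlapping gene, which lies on the same strand. FOXM1 overlaps RHNO1 and ITFG2, LPCAT3 overlaps C1S and EMG1, EGLN3 overlaps SPTSSA, and FADS1 overlaps FADS2. SREBF1 overlaps RAI1 and MIR33B, BNIP3L overlaps PNMA2, MAP1LC3B overlaps FBXO31, and CCNB2 and BCAT2 overlap genes without a symbol. The overlapping gene was the more abundant one for LPCAT3 (C1S at a mean of 14.1 FPKM against 2.08), EGLN3 (SPTSSA at 25.4 against 3.23) and FADS1 (FADS2 at 23 against 18.5).

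**Figure D2:**
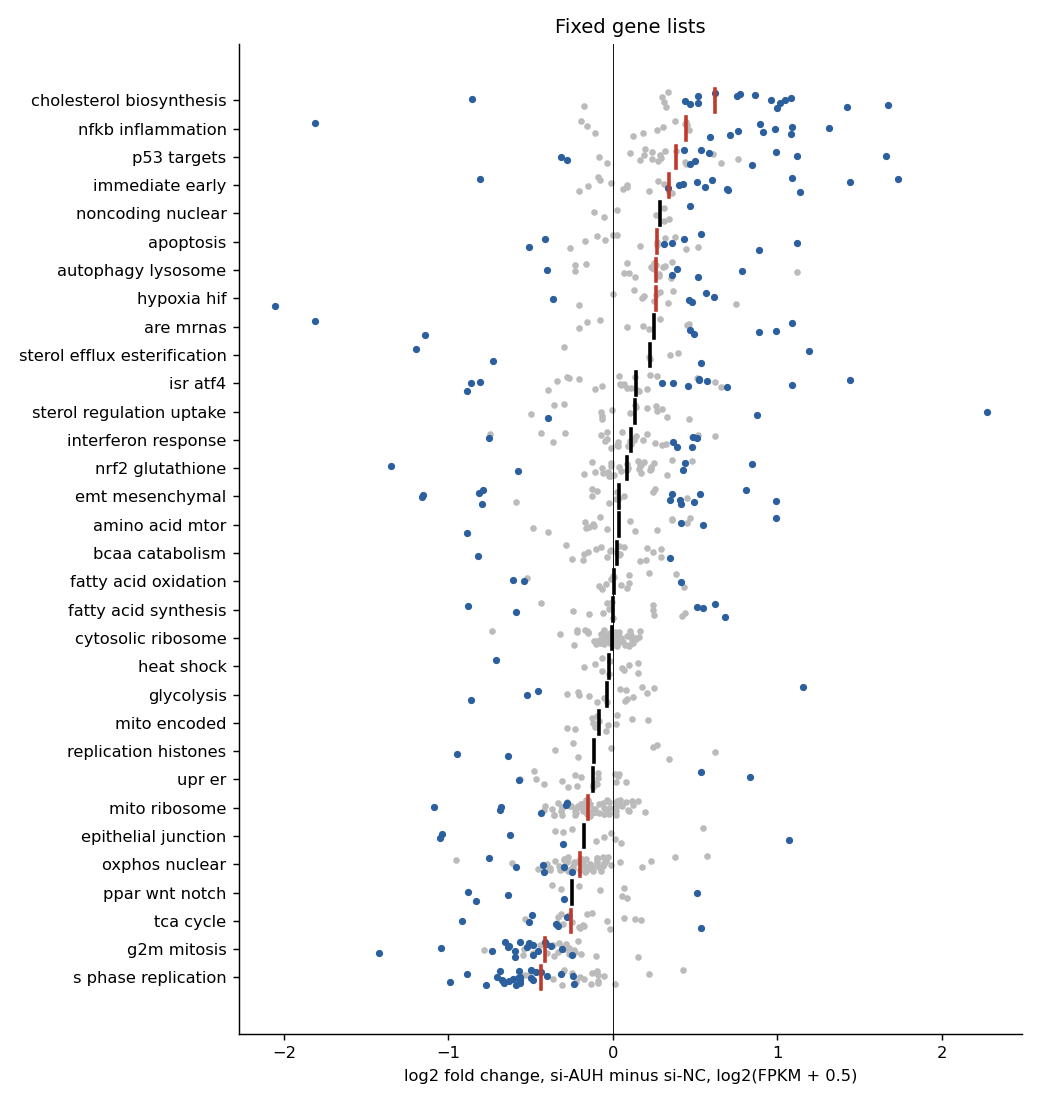
log2 fold change, si-AUH minus si-NC, on the log2(FPKM + 0.5) scale, of each tested gene (points) in the 32 tested lists (rows). Blue points passed the limma threshold and grey points did not; bars mark list medians, red for the 12 lists past the camera threshold at the preset correlation, from -0.44 for DNA replication to 0.62 for cholesterol biosynthesis.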

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

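voom on recovered reads, the 2 left-out libraries, the mitochondrial covariate, the length and GC corrections and the fit without word genes were chosen after seeing the data. AUH stayed lower and past the limma threshold in each fit that tested it; the filter at 5 FPKM removed it. The cholesterol list (median 0.62) kept its direction throughout and missed the threshold only with an estimated correlation (median 0.622, adjusted p = 0.0685; other settings, 2.75e-13 to 0.000231). The branched-chain amino acid list never passed. The counts of genes (819 higher, 1189 lower) became 437 and 710 without a filter on low values, which tests 33293 genes, 148 and 313 with the replicate number as a block, and 69 and 135 at an absolute log2 fold change of at least 1. They became 1969 and 2428 with the mitochondrial share as covariate, and 1332 and 1683 after removing trends on transcript length and GC content; the cause was not tested. Leaving out 1 library gave 327 to 687 higher and 564 to 1079 lower, with fewer samples. Lists past the threshold (12) became 0 with an estimated correlation and 16 in fry, which does not compare a list with other genes: 3 lost the call and 7 gained it. In voom on the recovered reads, 974 genes were higher and 1354 lower.

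Of 114 genes named by the rule and past the threshold, 71 kept the call in every leave-one-out fit, 43 lost it in at least 1, and 0 changed sign. Genes named after their values were seen are not in this count, and most of them lost the call in at least 1 fit. Same-numbered libraries did not deviate together (correlations -0.29, -0.25 and 0.15), and 0 of 3 si-NC libraries correlated best with their own number in si-AUH, so the block removes degrees of freedom without a pairing in the design. With the block, 12 lists passed. Across all settings, single named genes, with those named after their values were seen, gave 2396 results on the same side. Another 372 were no longer past the threshold and 26 newly past it, and other lists gave 607, 22 and 28. No gene or list past the threshold in more than 1 setting had values of both signs there. List medians near 0 did change sign: without 1 library, branched-chain amino acid breakdown ranged from -0.0258 to 0.0418, and cytosolic ribosome went from -0.0028 to 0.126 without si-AUH replicate 2. Low genes limit precision: AUH itself rests on 21 to 166 reads per library.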

Other observations

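The tests of both siRNA strands, of deposited gene length, of other splits of the libraries, of the cholesterol list, of the libraries that stand apart and of AU-rich words and mRNAs were chosen after the results were seen.

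Other fixed lists held genes that moved in opposite directions. Of 14 epithelial junction genes, the claudin gene CLDN1 rose 2.11-fold, while PKP3, a desmosomal plakophilin, fell 2.12-fold, CLDN2 2.16-fold and E-cadherin (CDH1) 1.58-fold. Of 25 mesenchymal genes, 8 rose and 5 fell, with the transglutaminase TGM2 down 2.32-fold and the integrin ITGA5 2.35-fold; SNAI1, TGFBI and COL1A1 also fell, and SNAI1 lost its call in 3 of 6 leave-one-out fits, with a highest limma adjusted p of 0.073. PKP3, CLDN2, TGM2, ITGA5 and, below, SLC7A5, SLC7A1, TALDO1 and TPI1 carry CAGGGAC or AGGGACA in the 3' UTR. CLDN2 overlaps MORC4 and TGM2 overlaps RPRD1B, and SLC7A5, below, overlaps MIR6775, so their levels are uncertain. Among 34 genes of the ATF4 stress response, 9 rose and 3 fell (SLC7A5, SHMT2 and SLC7A1). PPP1R15A, which ends the stress block on translation, rose 2.16-fold, and SLC7A5, a transporter of leucine and other large neutral amino acids, fell from 805 ± 99.99 to 433 ± 26.5 FPKM (SD, n = 3 each). Of 35 genes of the NRF2 and glutathione list, 3 rose and 2 fell, with a median of 0.09. NR0B1 rose 1.80-fold, GCLC, of glutathione synthesis, 1.36-fold and the thioredoxin reductase gene TXNRD1 1.35-fold, while TALDO1 and PGD of the pentose phosphate pathway fell 2.56-fold and 1.49-fold. TXNRD1 was named after its values were seen, and NR0B1, GCLC and TXNRD1 lost their calls in 3, 2 and 4 of the 6 leave-one-out fits. TXNRD1 overlaps RPL18AP3 and EID3, and GCLC overlaps expressed genes without a symbol, so their levels are uncertain too. Of 19 glycolysis genes, 3 fell and 1 rose. TPI1, which shares sequence with the pseudogene TPI1P1 and overlaps SPSB2, fell 1.82-fold, and ALDOC rose 3.45-fold. None of these 5 lists passed at the preset correlation (limma camera, adjusted p = 0.205, 0.599, 0.0737, 0.0658 and 0.761). In fry the epithelial, ATF4 and glycolysis lists passed (limma fry, adjusted p = 0.0186, 0.00767 and 0.0107). Without si-NC replicate 1 and si-AUH replicate 2 the ATF4 and NRF2 lists passed as higher (limma camera, adjusted p = 0.0389 and 0.0489). The NRF2 list also passed without si-NC replicate 3 and without si-AUH replicate 2 (limma camera, adjusted p = 0.0432 and 0.0206), under quantile normalization (0.0271) and at a mean of at least 5 FPKM (0.0291). Without a filter on low values both passed (limma camera, adjusted p = 0.0338 and 0.031), as they did after removing trends on deposited gene length and GC content (0.042 each); with transcript length the NRF2 list passed (0.0393). The ATF4 list also passed with the mitochondrial share as covariate (limma camera, adjusted p = 0.0409) and among genes without the words CAGGGAC and AGGGACA (0.0201). In the remaining settings neither passed.

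Of the other tested lists, 34 interferon genes gave adjusted p = 0.0718 in limma camera, 12 Wnt, Hippo and Notch readouts 0.0737, 16 mRNAs known for AU-rich elements 0.138, 8 nuclear noncoding RNAs 0.138 and 23 endoplasmic reticulum stress genes 0.161. In fry the Wnt, Hippo and Notch list passed (limma fry, adjusted p = 0.00247), and in camera it passed without a filter on low values (0.0402). The endoplasmic reticulum list passed as lower without si-NC replicate 1 and si-AUH replicate 2 (median -0.15; limma camera, adjusted p = 0.0389) and without a filter on low values (0.0189). The lists of amino acid sensing (20 genes), fatty acid oxidation (17), replication histones (10) and heat shock (12) gave limma camera adjusted p = 0.359, 0.681, 0.705 and 0.753, and sterol efflux and esterification 0.359; heat shock and sterol efflux passed in fry (limma fry, adjusted p = 0.00688 and 0.0151). Of 68 cytosolic ribosome genes, 0 passed in limma, with a median of -0.0028 (camera adjusted p = 0.866); without si-AUH replicate 2 that list passed, with a median of 0.13. The interferon list passed without si-AUH replicate 3 (limma camera, adjusted p = 0.0478), at a mean of at least 5 FPKM (0.0361) and without a filter on low values (0.0189). Too few genes were expressed to test alveolar type 2 markers (3), ketone body genes (3), markers of other cell lines (1), stromal markers (1, COL1A1) and immune cell markers (0). COL1A1 fell from 4.48 ± 0.37 to 2.38 ± 0.215 FPKM (SD, n = 3 each; limma adjusted p = 0.00427).

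More genes fell than rose (1189 against 819), and the lowest words in 3' UTRs were AGGGACA (1349 genes), of which the AUH mRNA holds only the reverse complement, and CAGGGAC (1428 genes), which it holds in sense at base 865 and as the reverse complement at base 714. Genes with AGGGACA had a median log2 fold change that differed by -0.115 from genes without it (95% bootstrap interval -0.143 to -0.086; z = -13.17), and genes with CAGGGAC, which 28% of other mRNAs also hold in sense, by -0.102 (-0.123 to -0.079; z = -12.12), against a lowest z of -4.91 in 100 shuffled runs. Without either word, 635 coding genes were higher and 706 lower, and with at least 1 of them 107 and 424. A refit on the 7820 genes without either word gave 805 higher and 816 lower. Of 123 called coding genes with a log2 fold change of -1 or lower, 78 (63.4%) held at least 1. The words were picked from these same fold changes, so these counts do not test them independently. In coding sequences and 5' UTRs, 0 words went below their shuffled runs. Length and GC content were argued against as the whole cause, since falls still outnumbered rises after their trends were removed. That criterion was taken up after the values were seen. The criterion written beforehand, for transcript length, was a cut in the count of falls, and the count was not cut. Among the 11495 genes with these values, 1207 were lower and 837 higher before the correction. After removing each library's trend on transcript length and GC content, 1683 were lower and 1332 higher, and with deposited gene length in its place 1520 and 1193. Counts rose in both directions, so the number of falls alone does not decide this. Median-of-ratios scaling gave 1114 lower against 904 higher, so that choice did not end the excess. Quantile normalization narrowed it to 1043 against 979, so scaling stays open, as do length and GC content as a part. Silencing of other mRNAs through the siRNA's seed may account for part of the falls. The sources used here do not give the siRNA's sequence, its site in AUH or whether a pool was used, so no known seed was matched. Whether both strands of a single siRNA take part stays open. A 23-base window of AUH held 6 of the 18 low words, on either strand, and 1.44% of other mRNAs held as many or more in one window. The AUH window is ATGTCCCTGGCCAAGGAGCTCAT at bases 712 to 734 of ENST00000375731, with GAGCTCA and its reverse complement TGAGCTC counted as 1.

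The rise of the cholesterol enzymes (median 0.62) was not accounted for by the technical settings tried. The median was 0.539 without si-NC replicate 1 and si-AUH replicate 2, 0.603 under quantile normalization and 0.61 or 0.582 after removing trends on GC content and deposited gene or transcript length, each past the camera threshold at the preset correlation; with an estimated correlation the list missed it (limma camera, adjusted p = 0.0685). Among the 16 list genes without either 3' UTR word the median was 0.764, with 14 higher and 0 lower in limma. The words were picked for falls in these same data, so a higher median without their carriers is no independent support. A response to lower AUH is a hypothesis consistent with these values, but an indirect effect of other silenced mRNAs was not tested and stays open, since no second siRNA or rescue was analysed here. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as large a median, the real one, and the highest other was 0.281. Each other split mixes the groups and so keeps part of the real difference, and 10 splits cannot give a share under 0.05.

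In the other splits, 0 genes passed in limma against 2008 in the real one (3843 at an unadjusted p under 0.05 in the real split), and 1 split of 10 reached that count, the real one. For lists past the threshold, 2 of the 10 splits gave 12 or more: the real split, and one that set si-NC replicates 1 and 2 with si-AUH replicate 2 against the rest, with 15. That split puts both libraries with more mitochondrial RNA on one side, but so do 3 others, with 11, 7 and 7 lists; splits other than the real one that part these libraries gave 6 to 10. Camera at the preset correlation called 6 or more lists in every split. The other splits mix the groups and so keep part of the real difference. Their counts of genes and lists therefore do not measure calls by chance, and 10 splits are too few for a share under 0.05.

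si-NC replicate 1 and si-AUH replicate 2 stood apart together on the second principal component (27.5% of variance), with scores of 22.6 and 25.3 against -15.5 to -9.95 in the others. An exchange of these libraries between groups is argued against by AUH, at 1.11 FPKM in si-AUH replicate 2 and 3.83 FPKM in si-NC replicate 1. Their shared deviation correlated with gene length across nuclear coding genes (Spearman rho 0.53; genes are not independent replicates), yet their deviations still correlated at 0.62 after removing trends on deposited gene length and GC content, from 0.71. Mitochondrial protein-coding genes, all under 2000 bases, deviated by a median of 0.6 while nuclear coding genes under 2000 bases deviated by -0.34. A length trend alone does not give this, but the first value restates the higher mitochondrial share of these libraries and is no independent test. The labels give no library batch or day, so a difference in handling stays open, as does one in the cells, and no biological explanation was tested.

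AUH is known for binding AU-rich RNA, so mRNAs with an AU-rich word were examined. The 3346 genes with TTATTTA in the 3' UTR differed from the others by 0.037 in median log2 fold change. The 95% bootstrap interval was 0.025 to 0.05, and the word's z was 3.45. Over all 15627 words in 100 shuffled runs, the lowest and highest z were -4.91 and 4.77. That range bounds a search over all words, so it cannot show whether TTATTTA, picked for a known function, differs from shuffled values of its own. The bootstrap interval resamples genes with the libraries held fixed and is not adjusted for UTR length or GC content. It gives a median shift under 0.1 at steady state in these libraries, but does not bound an effect of the knockdown. The 16 tested mRNAs known for AU-rich elements had a median of 0.252 (95% bootstrap interval -0.078 to 0.47; 11 above 0; limma camera, adjusted p = 0.138), and at a mean of at least 5 FPKM the list passed as higher, with a median of 0.452 (limma camera, adjusted p = 0.0291). An effect on this smaller set therefore stays open.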
